A study of Mus musculus with 6 samples.

How the data were processed

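The data are probe set signals from 6 mouse expression arrays, 1 per sample, with 3 samples of LECs from healthy mammary skin and 3 of LECs from MDA-MB-435 tumours. Per the labels' protocols, sections were briefly stained for LYVE-1, LECs were isolated by laser capture microdissection, RNA was extracted with a micro column kit, and a single round of Ribo-SPIA amplification preceded biotin labelling. The authors deposited intensity values on a linear scale, which the submitters' processing notes tie to RMA, a method that corrects background, quantile-normalizes probes and summarises them per probe set. The RMA software, its version, the probe set definitions and any filter are not given in the sources used here. RMA values are usually log2, so the linear scale was read from the values: array medians lay between 9.49 and 10.93, maxima reached 33060 and no value was below 0. An amplification from the few cells of a microdissected sample adds spread between samples, and a normalization that equalises arrays removes any overall difference in RNA amount.

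Values were taken to log2 without a pseudocount or a further normalization. The 64 control probe sets were left out of the tests, and all other 45037 were kept whatever their signal. Every column of the table belonged to a sample. Gene symbols came from the platform annotation, in which 34945 probe sets had a single symbol, 932 several and 9160 none. Of those with a single symbol, 34741 matched the RefSeq gene table by Entrez identifier and none had its symbol changed. Genes were named only from probe sets with a single symbol, except Rpl21 and Gm5528 among the results flagged for a closer look. A gene was represented by the probe set with the highest mean over all 6 arrays, which gave 18193 genes. No coordinates are given, since the sources name no genome build.

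Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, prior degrees of freedom 2.82), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. No block was used, since the labels name no animal, litter or day behind a replicate number. Gene lists, 38 in all with 17 of cell type markers, were fixed before the data were examined and needed at least 5 measured members. They were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Members were adjusted both over all probe sets and over the list alone. Array-level values were compared by exact two-sided permutation tests.

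The genes named were set by a rule fixed beforehand. It took up to 14 genes per direction that passed the threshold with groups that did not overlap, filled each direction up to 5 genes by smallest p, and passed over probe sets ending in _x_at. It added Lyve1, Prox1, Pdpn, Flt4 and Pecam1, and up to 4 members with the smallest p of each list described. The probe set 1441304_at has no symbol and was named after its values were seen, because it is 1 of only 2 that passed.

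The arrays give signal over background rather than depth. The 95th percentile of 27 bacterial control probe sets, taken here as background because no label says that their transcripts were added, lay between 2.96 and 3.91 (log2), and on average 49.3% of probe sets in healthy skin and 44.9% in tumours were above their array's value (exact permutation p = 0.4, n = 3). In simulated data with the spread of these arrays, limma recovered 0 of 50 probe sets planted with a log2 change of 1, 9 of 50 with 2, 34 of 50 with 4 and 46 of 50 with 8, and called 2 unchanged ones. In 20 simulations without any change it called at most 1 probe set. A planted list was found at a camera adjusted p of 3.6e-15 and 0 lists that share no member with it were called. The simulated noise was independent between probe sets, whereas members of real lists moved together (estimated correlation 0.253 for keratinocyte markers). The simulation therefore cannot show how often camera calls such lists falsely.

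Alternatives set before the data were examined were a filter on dim probe sets, quantile normalization, centring on array medians, the replicate number as a block, eBayes with trend and robust options, array weights, each array left out, a log2 fold minimum of 1, an unmoderated statistic, other ways to summarise a gene, and other list tests. A covariate and a block for the hybridization-control level (the mean of 10 control probe sets), and lists without shared members, were added after seeing the data.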

Results

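Lymphatic endothelial cells (LECs), the cells that line lymphatic vessels, were profiled on 6 mouse Affymetrix expression arrays. Of these, 3 samples came from healthy mammary skin of nude mice and 3 from tumours that had grown for 8 weeks from the human cancer line MDA-MB-435, a line long used as a breast cancer model and later traced to a melanoma. Cells were located on tissue sections by a brief stain for LYVE-1, a hyaluronan receptor of lymphatic vessels, and were cut out by laser capture microdissection. Each array gave a signal for 45101 probe sets, of which 45037 were tested after 64 control probe sets had been left out. The design text also speaks of blood endothelial cells, which were not analysed here. The single comparison of the design asks which genes differ between tumour-associated and normal LECs. The labels call the samples biological replicates without saying that each came from its own animal. The limma p-values therefore judge differences against the spread between these samples, and the number of arrays limits their precision. Camera instead compares the members of a list with the other genes. At its preset correlation it makes only a fixed allowance for members that move together.

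The samples of tumour-associated LECs had more signal for endothelial genes and matrix proteases, and less for keratinocyte and lipid-handling genes, than those from healthy skin. Healthy-skin samples had strong signal for keratinocyte genes such as Krt10 (9.66 ± 0.58, log2). Changes within LECs and differences in the other cells captured therefore cannot be told apart. Igfbp3, which encodes a secreted binding protein of insulin-like growth factors, rose from 3.35 ± 0.19 to 7.54 ± 0.26 on the log2 scale (SD, n = 3 arrays per group), a log2 change of 4.19 with a standard error of 0.28. As a list, the keratinocyte markers fell, with a median log2 change of -2.39 over 18 measured genes. The pan-endothelial markers rose as a list by a median of 0.91 over 23 genes, and the matrix proteases and their inhibitors by 1.10 over 26 genes. These lists had camera adjusted p of 9.21e-17, 4.65e-07 and 6.24e-08, and adjusted p = 0.187, 0.111 and 0.111 with an estimated correlation. The lipid-handling list, whose camera adjusted p was 1.47e-05, had 0.262 with an estimated correlation, 0.21 with fry and 0.445 by camera with the hybridization-control level as a covariate. Another split of the arrays gave this list an unadjusted camera p of 2.86e-06, against 1.54e-06 for the real one. For keratinocyte markers the lowest unadjusted camera p of another split was 7.24e-09, against 2.42e-18. Matrix proteases had 1.76e-07 against 3.28e-09, and pan-endothelial markers 0.0158 against 3.67e-08.

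Over all probe sets, limma called 2 at an adjusted p under 0.05, both higher in the tumour samples, and 1 of them represented a named gene. These were Igfbp3 (1458268_s_at, adjusted p = 0.0412) and 1441304_at, which carries no gene symbol and went from 2.38 ± 0.09 to 10.63 ± 0.99 (log2 change 8.25, standard error 0.50, limma adjusted p = 0.0412). The latter is 1 of 7 probe sets with log2 rises above 5 and an unadjusted limma p under 0.001. The second Igfbp3 probe set, 1423062_at, had 2.96 ± 0.15 in healthy skin and 6.96 ± 1.77 in tumours, and did not pass (limma adjusted p = 0.441). At an unadjusted p under 0.05 there were 2863 probe sets, 1275 higher and 1588 lower, and 22 had an adjusted p under 0.1, 6 higher and 16 lower. The 3 values of each group did not overlap in 11.1% of probe sets, against 10% given by chance for 3 against 3 arrays. Igfbp3 kept its call without tumour replicate 2 (limma adjusted p = 0.0454) and lost it without healthy-skin replicate 1, 2 or 3 (0.0854, 0.185 and 0.0866), without tumour replicate 1 or 3 (0.285 and 0.126) and after centring on array medians (0.0559). In each of those fits no probe set was called.

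The genes that the naming rule took next by p did not pass the threshold, and their values are given as measured. The rule skipped probe sets ending in _x_at, among them that of Sbsn (difference -3.59, limma adjusted p = 0.0541). C5ar1, the receptor for complement fragment C5a, had 3.44 ± 0.51 in healthy skin and 7.53 ± 0.11 in tumours (log2 difference 4.09, limma adjusted p = 0.0508), while its other probe set differed by 0.43. Nmb, which encodes the peptide neuromedin B, and Ackr2, a decoy receptor for inflammatory chemokines found on lymphatic endothelium, each differed by 2.56 (limma adjusted p = 0.185 for both). The other Ackr2 probe sets differed by 0.57 and 0.61. Cldn5, a tight junction protein of endothelium, had 5.36 ± 0.40 and 7.53 ± 0.34 (difference 2.17, limma adjusted p = 0.244). On the lower side, Xbp1, a transcription factor of the unfolded protein response, differed by -3.94 (limma adjusted p = 0.0508), but its other 3 probe sets by -0.56, -1.02 and -1.17. The long non-coding RNA Miat differed by -4.14 (limma adjusted p = 0.0508) and by -0.39 on its other probe set. Peg3, an imprinted zinc finger gene, differed by -3.75, and Prr15 by -4.40 (limma adjusted p = 0.0541 for both). Slc16a13, a member of the monocarboxylate transporter family, differed by -3.75 (limma adjusted p = 0.0739). The weaker probe sets of Peg3 and Prr15 differed by between -1.16 and 0.32.

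**Figure D1:**
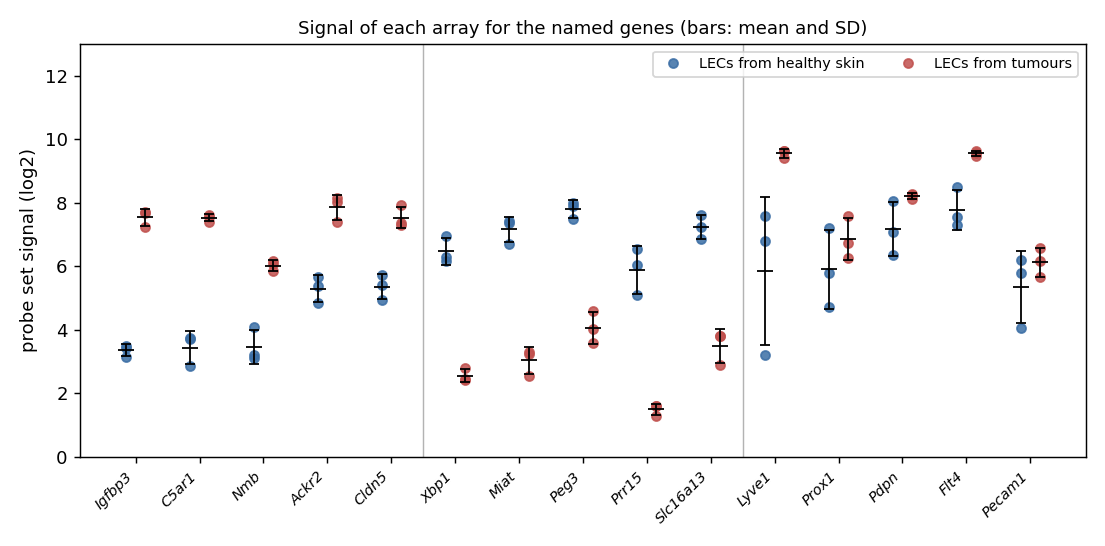
Probe set signal (log2, vertical axis) of each array for the named genes (horizontal axis), with LECs from healthy skin in blue and from tumours in red; bars give the mean and SD of 3 arrays. The first 5 genes have the smallest p among higher genes, the next 5 among lower genes, and the last 5 are lymphatic and endothelial markers, of which Lyve1 spread most in healthy skin (SD 2.34).

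The LEC marker list rose by a median log2 change of 0.47 over 19 genes, 15 of them with positive values (camera adjusted p = 0.0134, and adjusted p = 0.281 with an estimated correlation). Over all probe sets no member passed, and adjusted over the list alone 2 rose, namely Itga9, an integrin subunit needed for lymphatic valves (log2 change 1.85), and Flt4, the VEGF-C receptor VEGFR-3 (1.77, from 7.79 ± 0.63 to 9.57 ± 0.07). Lyve1, whose protein was the stain used to find the cells and which is therefore no independent finding, had 5.87 ± 2.34 in healthy skin and 9.57 ± 0.14 in tumours (limma adjusted p = 0.626). Its second probe set went from 4.08 ± 0.51 to 7.09 ± 0.56 (limma adjusted p = 0.185). The first had 3.21 in healthy-skin replicate 1, below that array's background of 3.81, and 7.58 and 6.81 in replicates 2 and 3. Pdpn, the membrane glycoprotein podoplanin, differed by 1.04 (limma adjusted p = 0.794). Prox1, the master transcription factor of lymphatic fate, differed by 0.95 (limma adjusted p = 0.87), with 0.84 and -1.11 on its other probe sets. Healthy-skin replicate 1 also had the lowest values of Prox1 (4.73), Pdpn (6.37) and Pecam1 (4.07). Its mean over the pan-endothelial list was yet the highest in healthy skin (4.665, against 4.536 and 4.319). On the same arrays the keratinocyte list was lower in every tumour sample. Without healthy-skin replicate 1 the LEC list had an adjusted p of 0.155 by camera, and without tumour replicate 2 one of 0.0509. Its call was also lost over the members that no other list holds, an alternative chosen after seeing the data (camera adjusted p = 0.269), on ranks (0.0589) and with fry (0.123).

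Of the 23 pan-endothelial markers, 21 had positive values, no member passed over all probe sets, and adjusted over the list alone 3 rose (camera adjusted p = 4.65e-07, and adjusted p = 0.111 with an estimated correlation). These were Cldn5, Cdh5, which encodes the adherens junction protein VE-cadherin (2.10), and Ecscr, an endothelial surface protein (1.84). Esam, another endothelial adhesion molecule, differed by 1.19, and Pecam1 by 0.78 (limma adjusted p = 0.873). The mean of this list was higher in each of the 3 tumour samples than in any healthy-skin sample, the reverse of the keratinocyte list, and fry, which asks whether the genes move one way on balance, gave an adjusted p of 0.00993. The list of endothelial junction genes rose by a median of 0.39 over 24 genes (camera adjusted p = 0.0285, and adjusted p = 0.281 with an estimated correlation). It shares Cldn5, Cdh5 and Esam with the pan-endothelial list, Cldn5 alone rose when adjusted over the list alone, and Afdn, the junction scaffold afadin, went the other way with -1.61. That call was lost without healthy-skin replicate 1 (adjusted p = 0.24) and without tumour replicate 1 (adjusted p = 0.108), and over members that no other list holds (adjusted p = 0.426). By contrast, the 20 measured markers of blood-vessel endothelium had a median of 0.19 and did not pass (camera adjusted p = 0.956), with Cd34 at -1.43, Rgcc at -2.32 and Aqp1 at 1.83.

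Growth factor and guidance genes rose as lists by small amounts. The lymphangiogenic growth factors and receptors had a median log2 change of 0.28 over 33 genes, 24 of them positive (camera adjusted p = 0.0134, and adjusted p = 0.254 with an estimated correlation). Adjusted over the list alone 2 rose, again Itga9 and Flt4, and none passed over all probe sets. Ephb4, an ephrin receptor of veins and lymphatics, differed by 1.47 and Angpt2, a ligand of the receptor TIE2, by 1.52. The semaphorin, ephrin and axon guidance list rose by a median of 0.32 over 37 genes (camera adjusted p = 0.0226, and adjusted p = 0.257 with an estimated correlation). Sema3a, a repulsive guidance cue, was its only member to rise when adjusted over the list alone (3.13), while Sema7a had 1.66 and the netrin receptor gene Unc5b 1.90. Efnb2, named outside the rule, belongs to both lists and entered them with 0.014. Another of its probe sets, 1419638_at, went the other way with -2.74 (limma adjusted p = 0.0784). Without healthy-skin replicate 1 both calls were lost (adjusted p = 0.15 and 0.215), and without tumour replicate 2 the guidance list had an adjusted p of 0.16 by camera. Over members that no other list holds neither was called (camera adjusted p = 0.861 for the lymphangiogenic list and 0.0736 for the guidance list).

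The matrix protease and inhibitor list rose with 24 of 26 members positive (camera adjusted p = 6.24e-08, and adjusted p = 0.111 with an estimated correlation). Adjusted over the list alone 8 rose, against none over all probe sets. Among them were the lysosomal protease gene Ctsb (2.80), the plasminogen activators Plat (1.88) and Plau (3.80, and 3.90 on its second probe set), and the aggrecan-cleaving protease gene Adamts5 (2.60). Relative to the healthy-skin mean the list averaged 1.42, 1.95 and 0.79 in tumour replicates 1, 2 and 3, in the same order as the pericyte markers given below, and replicate 2 was also highest in macrophage markers (1.92). That order is not particular to pericytes. Fibroblast markers (0.29, 0.68 and -1.88) and the oxidative phosphorylation list (-0.74, -0.13 and -1.52) had it too. It is also the reverse of the order of the hybridization-control level (12.30, 11.60 and 12.60). The basement membrane list rose by a median of 0.66 over 21 genes (camera adjusted p = 0.0319, and adjusted p = 0.43 with an estimated correlation). None of its members passed either adjustment, and its lowest p belonged to the collagen IV chains Col4a1 (3.06) and Col4a2 (2.70), fibronectin Fn1 (1.96) and laminin Lamc1 (1.52). The interstitial matrix list was not called (median 0.05, camera adjusted p = 0.789). Relative to the healthy-skin mean, the basement membrane list averaged 0.91, 1.00 and 0.16 in tumour replicates 1, 2 and 3, and the pericyte and smooth muscle markers 0.62, 0.85 and -0.06 on the same arrays (camera adjusted p = 0.0545). The basement membrane call was lost without healthy-skin replicate 1 (adjusted p = 0.24), tumour replicate 1 (0.063) or tumour replicate 2 (0.297), and over members that no other list holds (0.0557). The tumour endothelial marker list rose by a median of 0.78 over 19 genes (camera adjusted p = 0.016, and adjusted p = 0.386 with an estimated correlation). No member passed either adjustment, and the smallest p were those of Ctsb and Angpt2, which other lists hold too, then Robo4 (1.17) and Pgf (0.94). This list averaged 0.74, 0.83 and 0.18 in the 3 tumour samples, in the same order as the pericyte and fibroblast markers. Over members that no other list holds it was not called (camera adjusted p = 0.701). Leaving out healthy-skin replicate 1, tumour replicate 1 or tumour replicate 2 ended that call (adjusted p = 0.361, 0.0516 and 0.083).

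Macrophage and interferon genes were highest in tumour replicate 2. The macrophage list rose by a median of 0.71 over 24 genes (camera adjusted p = 0.000611, and adjusted p = 0.515 with an estimated correlation). Relative to the healthy-skin mean, its members averaged 1.92 (log2) in tumour replicate 2 but 0.19 and 0.21 in replicates 1 and 3, and without replicate 2 the adjusted p was 0.22. No member passed either adjustment; Ms4a7, a tetraspanning membrane protein of macrophages, differed by 2.98, and Csf1r, the receptor for colony-stimulating factor 1, by 1.83. The type I interferon list rose by a median of 0.59 over 26 genes (camera adjusted p = 0.0116, and adjusted p = 0.58 with an estimated correlation). Rsad2, the antiviral protein viperin, alone rose when adjusted over the list alone (2.45), and Oas1a had 1.21. Here too replicate 2 was highest (1.10, against 0.01 and 0.52), and the call was lost without it (adjusted p = 0.398) and without healthy-skin replicate 2 (adjusted p = 0.167).

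Genes of the skin surface were lower in the tumour samples. Whether these captures held fewer skin cells or the LECs themselves differed cannot be told from these values. Of the 18 keratinocyte markers, 17 had negative values, none passed over all probe sets, and adjusted over the list alone 10 fell (camera adjusted p = 9.21e-17, and adjusted p = 0.187 with an estimated correlation). The suprabasal keratin Krt10 went from 9.66 ± 0.58 to 4.75 ± 1.41 (log2 change -4.91), its partner Krt1 changed by -2.37, and the differentiation genes Sbsn and Krtdap by -3.59 and -2.69. The mean of the list's members in healthy skin was 7.04, 7.35 and 8.00 (log2) in replicates 1, 2 and 3, against 5.91, 5.45 and 4.05 in the tumour samples.

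The fatty acid and lipid list fell by a median of -0.93 over 30 genes, 19 of them negative (camera adjusted p = 1.47e-05, and adjusted p = 0.262 with an estimated correlation). Adjusted over the list alone 9 fell, against none over all probe sets. These included Srebf1, the transcription factor of lipid synthesis (-2.10), fatty acid synthase Fasn (-1.73), Hmgcs1 of the mevalonate pathway (-3.17) and the fatty acid transporter gene Slc27a4 (-1.48). The adipocyte list fell with a median of -0.26 and a mean of -0.88 over 17 genes (camera adjusted p = 0.0285, and adjusted p = 0.281 with an estimated correlation). Its smallest p belonged to Lpl (-3.58), Scd1 (-6.07) and Cd36 (-2.55), genes of lipid uptake and desaturation that the lipid list also holds, followed by the lipid droplet gene Plin4 (5.79 and 4.79 in healthy skin and tumours), and none passed when adjusted over the list alone. Without healthy-skin replicate 1, healthy-skin replicate 2 or tumour replicate 1 the adipocyte call was lost (adjusted p = 0.155, 0.072 and 0.0909), as it was over members that no other list holds (adjusted p = 0.701). The oxidative phosphorylation list fell by a median of -0.67, with 30 of 31 genes negative but none past either adjustment (camera adjusted p = 3.47e-05, and adjusted p = 0.459 with an estimated correlation). Ndufa1 and Ndufb5, subunits of respiratory complex I, differed by -1.98 and -2.62. The mean of the oxidative phosphorylation list in tumour replicate 2 (6.78) lay above that in healthy-skin replicate 1 (6.42), and its direction reversed with the hybridization-control level as a covariate (camera adjusted p = 0.151). Of the 10 splits of the arrays, the real one included, 3 gave this list a camera p as low as the real one and 2 a mean shift as large.

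**Figure D2:**
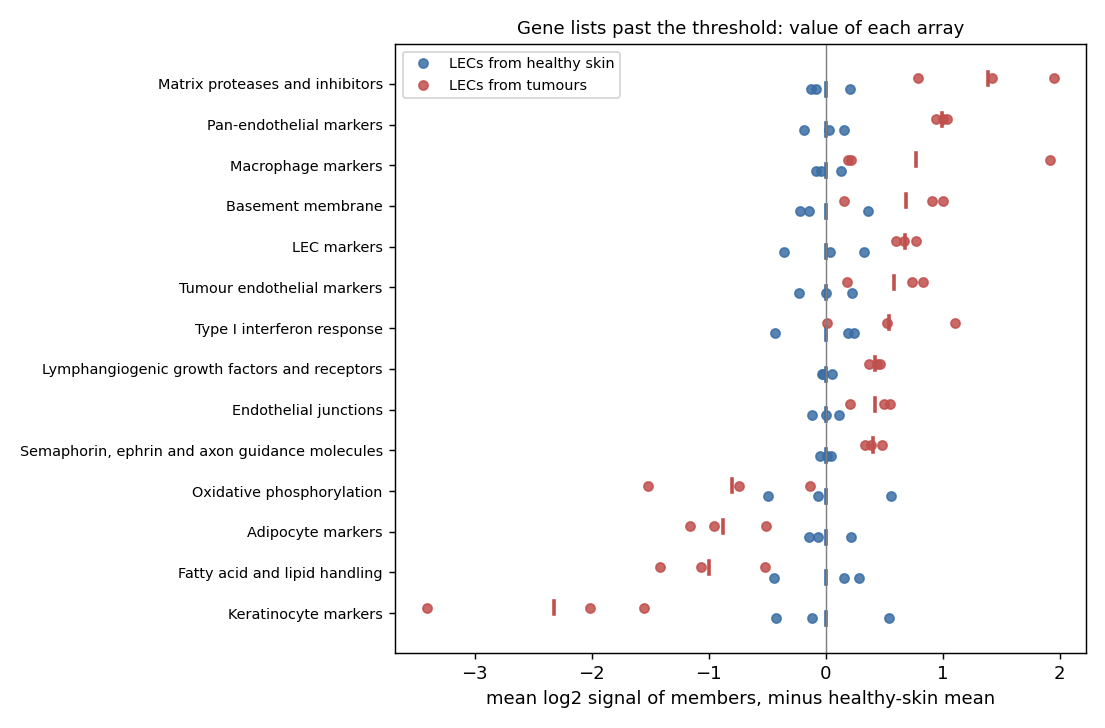
Mean log2 signal of the measured members of each of the 14 gene lists past the threshold (vertical axis), minus the mean of the healthy-skin arrays (horizontal axis, log2 units); points are arrays, vertical ticks group means, blue healthy skin and red tumours. Keratinocyte markers lie lowest in tumours and matrix proteases highest, and the macrophage value of tumour replicate 2 (1.92) stands apart from 0.19 and 0.21.

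In all, 14 of 38 lists passed with the preset correlation, 10 higher and 4 lower, and 0 of 38 with an estimated one, while fry called 5, all of them among the 14: the keratinocyte, matrix protease, pan-endothelial, lymphangiogenic and guidance lists. Camera on ranks did not call the LEC, adipocyte, lymphangiogenic, basement membrane, junction and guidance lists, and with array weights it did not call the LEC, macrophage, interferon, lymphangiogenic, tumour endothelial, basement membrane and guidance lists. Other splits of the 6 arrays gave a lower camera p and a larger mean shift for the interferon, tumour endothelial, basement membrane and oxidative phosphorylation lists, and a lower p alone for the LEC, macrophage, junction and guidance lists. The arrays also differed in their hybridization-control level, which crosses the groups but averaged 11.31 in healthy skin and 12.17 in tumours (exact permutation p = 0.2, n = 3). Hybridization controls, bacterial transcripts added in fixed amounts, averaged 11.96, 12.30 and 12.60 (log2) in healthy-skin replicate 1 and tumour replicates 1 and 3, and 10.97, 10.99 and 11.60 in the other 3 samples. Each set holds only 1 sample of a group, tumour replicate 2 in the low set and healthy-skin replicate 1 in the high set. Within the low-control and the high-control set, the keratinocyte list had median differences of -1.86 and -1.88 and the pan-endothelial list 0.73 and 0.78. The same pairs of values were 1.64 and 0.97 for matrix proteases, -0.99 and -0.55 for lipid handling, 0.38 and 0.89 for LEC markers, 0.38 and 0.41 for lymphangiogenic factors, 0.61 and 0.23 for guidance molecules, 0.19 and 0.74 for junctions, 0.27 and 0.59 for tumour endothelial markers, -0.21 and -0.44 for adipocyte markers, 2.01 and 0.36 for macrophage markers, 1.34 and -0.03 for the interferon response, 0.91 and 0.02 for basement membrane, and -0.38 and -0.20 for oxidative phosphorylation. With the control level as a covariate, chosen after seeing the data, the oxidative phosphorylation list changed direction (camera adjusted p = 0.151) and the lipid list lost its call (camera adjusted p = 0.445).

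Pearson correlations over probe sets were 0.808 to 0.846 within healthy skin, 0.814 to 0.864 within tumours and 0.783 to 0.837 between them. The log2 difference between 3-prime and 5-prime Gapdh control probe sets, a measure of RNA integrity, was 3.24 ± 0.47 in healthy skin and 2.85 ± 1.09 in tumours (exact two-sided permutation p = 0.6, n = 3 per group), and for beta-actin 0.10 ± 0.37 and 0.14 ± 0.67 (exact permutation p = 0.9, n = 3). Between 3-prime and middle probe sets the difference was 2.52 ± 0.43 and 1.76 ± 1.02 for Gapdh and 0.33 ± 0.86 and 1.30 ± 0.36 for beta-actin (exact permutation p = 0.3 for both, n = 3). With 3 against 3 samples the smallest p this test allows is 0.1, so it could not pass 0.05.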

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

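Of the tests below, those on the hybridization-control level, on dilution by epidermal cells and on the probe sets with steep rises were chosen only after the result was seen, as were the counts of probe sets and genes over other splits; the second epidermal and sebaceous lists were written before their values were seen, except that of Calml3.

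Among the 64 control probe sets, which the gene and list tests left out but which the array-level tests of Gapdh, beta-actin and hybridization controls used in part, 4 had all tumour values above all healthy-skin values, where chance gives 5%. The 5-prime probe set of 18S ribosomal RNA was higher by 0.567 (12.29 ± 0.09 against 12.85 ± 0.11, log2, SD, n = 3). The 5-prime beta-actin probe set was higher by 1.389, and the 5-prime and middle Gapdh probe sets by 1.229 and 1.595. Groups of 3 are too small for a check of single outlying samples, and there was no second contrast to compare.

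The first pattern is that keratinocyte and lipid-handling lists were lower in the tumour samples. Whether the arrays' hybridization-control level is the whole cause cannot be decided by camera at its preset correlation. At that setting another split of the arrays gave the keratinocyte list an unadjusted camera p of 7.24e-09. The keratinocyte list kept a camera adjusted p of 5.02e-12 with a block for the level and 1.42e-05 with the level as a covariate. The lipid list had 0.0015 with the block and 0.445 with the covariate. The block alone does not remove the level, which was higher in tumour samples within each set (11.60 against 10.97 and 10.99, and 12.30 and 12.60 against 11.96). Sebaceous gland cells caught in the healthy-skin captures are a candidate source: a list of 8 measured sebaceous genes had a median of -2.57 (camera adjusted p = 3.83e-08, and unadjusted p = 0.0559 with an estimated correlation), and its most abundant gene Far2 went from 10.48 ± 0.84 to 5.16 ± 2.23. Epidermal cells may add to this and stay open, because a second epidermal list had a median of -0.25 over 35 genes, 10 lower and 0 higher at an unadjusted p under 0.05 (camera adjusted p = 8.59e-07, and unadjusted p = 0.0071 with an estimated correlation), with Elovl4 at -5.48 and Krt77 at -3.20 beside Ivl at -0.08, and it shares Krt79 with the sebaceous list. The capture of LYVE-1-stained vessels was meant to exclude both cell types. Healthy-skin samples still had strong signal for the keratinocyte genes Krt5 (10.3 ± 0.4) and Krt10 (9.7 ± 0.6), so the protocol does not argue against such cells. A lower lipid synthesis of tumour-associated LECs themselves stays open and untested.

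The second pattern is that pan-endothelial genes were higher. With the block for the control level the list kept a camera adjusted p of 1.98e-07, although the block does not fully remove the level. With the level as a covariate it kept 9.94e-06. The same fit called the interstitial matrix and ribosomal protein lists (camera adjusted p = 5.66e-06 and 6.85e-07), which the main fit did not call. The kept call therefore cannot decide whether the level is the whole cause. If epidermal cells alone diluted the healthy captures, markers of other cell types should rise alike, yet the endothelial list exceeded the fibroblast list by 1.30 (log2, standard error 0.89, exact permutation p = 0.2, n = 3). That difference is too uncertain to decide, so a purer capture and a change within LECs cannot be told apart.

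The third pattern is a set of 7 probe sets with log2 rises above 5 and p under 0.001, of which 5 had no gene symbol, against 1 of 4 falling as much (Fisher exact p = 0.242) and 20.3% of all probe sets; 1441304_at, 1 of the only 2 probe sets called, belongs to it. The other 2 were annotated to Rpl27a and, for 1459002_at, to both Gm5528 and Rpl21. Rpl21 and Rpl27a do not account for the pattern, since the 5 other probe sets annotated to them had a median of -0.048. Most of those 5 were annotated to further genes as well. Less labelled target on some arrays is argued against as well, because these probe sets differed by a median of 3.06 (range 1.32 to 3.81) between tumour replicates 3 and 2 while the hybridization controls differed by 0.99. All 7 probe sets ordered the tumour samples the same way, replicate 3 over 1 over 2, as a single source of RNA that varies in amount would, although the hybridization controls gave that order too. RNA of the human tumour cells could be that source, but the melanocyte list (median 0.20) decides nothing, since mouse probes need not bind human transcripts.

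The 10 ways of splitting the arrays, the real one included, are too few for a share under 0.05. The real split gave 2 probe sets and the highest other 0, with 1 of 10 splits as large. For genes the real value was 1 and the highest other 0, again 1 of 10 splits. For lists the real value was 14 and the highest other 15, so 2 of 10 splits gave as many. The split that follows the hybridization-control level gave 4934 probe sets at an unadjusted p under 0.05 by limma, against 2863 for the real one, and 11 lists, which points to a structure of the samples that crosses the groups. It is partly tied to them, since 2 of the 3 arrays with a high level are tumour samples and the level averaged 12.17 in tumours and 11.31 in healthy skin (exact permutation p = 0.2, n = 3).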

How the results depend on the processing

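The hybridization-control fits and the lists without shared members were chosen after seeing the data. Signal over background limits dim genes, and the cause of a change was not tested unless stated. From 2 probe sets, 1 gene and 14 lists, the dim filter, which tested 22518 probe sets, gave 19 probe sets and 9 genes, and array weights 22 and 10 with 7 lists. Centring on array medians gave 0 probe sets and 0 genes, as did the hybridization-control covariate and block. eBayes with trend and robust options gave 1 and 0, and the ordinary t statistic 1 probe set, which was not among the 2. Quantile normalization gave 1 higher and 1 lower in place of 2 higher. Averaging a gene's probe sets gave 0 genes, and so did leaving out _x_at and _s_at probe sets. Lists numbered 0 with an estimated correlation, 8 on ranks, 5 with fry and 7 without shared members. Leaving out 1 array gave 0 to 23 probe sets, 0 to 12 genes and 7 to 17 lists; 23 and 12 came without tumour replicate 2, 0 and 0 without each of the others, 7 lists without healthy-skin replicate 1. Where 0 were called, limma had 2167 to 3726 probe sets at an unadjusted p under 0.05. With the replicate number as a block there were 0 probe sets, 0 genes and 16 lists; same-numbered samples correlated at 0.044, 0.10 and -0.013 in their deviations, and not every sample correlated best with its own number. The median of all probe sets was 0.06, and 0.04 and 0.02 after quantile normalization and centring.

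Of 266 alternatives of the called lists, 200 kept the call, 65 lost it and 1 reversed; keratinocyte, pan-endothelial and matrix protease lists lost theirs only with an estimated correlation (18 of 19 kept). Under the hybridization-control covariate, directions reversed for oxidative phosphorylation (adjusted p = 0.151), and for lists not called before: fibroblast 0.0259, MHC class I 0.00133, interstitial matrix 5.66e-06 and ribosomal proteins 6.85e-07. The interstitial matrix list ranged from 0.0126 (without tumour replicate 3, reversed) to 0.794 over arrays left out. Among 453 alternatives of uncalled lists, 24 were newly called (8 hypoxia, 7 pericyte, 4 lysosome, and immediate early, fibroblast, both MHC and ribosomal lists with 1 each), and 65 flips with no call in either fit were not counted as reversals. Genes named by p and the fixed markers kept direction in all 255 alternatives, 230 on the same side of the threshold, 12 newly past it and 13, all of Igfbp3, no longer past it. Differences between control probe sets kept direction against the middle probe set, at -0.759 for Gapdh and 0.963 for beta-actin.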

Other observations

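Several gene groups that the main comparison did not call held single genes with sizeable differences. The pericyte and smooth muscle list had a median of 0.57 over 16 genes (camera adjusted p = 0.0545), with Notch3 at 1.32 and the proteoglycan gene Cspg4 at 1.19. It was called higher in 7 of the alternatives, among them quantile normalization (camera adjusted p = 0.0464) and the fit without tumour replicate 3 (0.00289). The hypoxia and glycolysis list had a median of 0.56 over 27 genes (camera adjusted p = 0.0758), with Ndrg1 at 1.70, P4ha1 at 1.71 and Vegfa at 1.27. It was called higher in 8 alternatives, among them the dim filter (camera adjusted p = 0.0282) and quantile normalization (0.0163); its mean lay 1.03 above healthy skin in tumour replicate 3 and 0.20 and 0.11 above it in replicates 1 and 2. Among inflammatory chemokines, cytokines and adhesion molecules the median was 0.02 (camera adjusted p = 0.988), yet Ackr2 rose when adjusted over the list alone (2.56) and Csf1, the growth factor of macrophages, had -2.39. In the unfolded protein response list, whose median was 0.04 and mean -0.21 (camera adjusted p = 0.301), Xbp1 alone fell when adjusted over the list alone (-3.94). In the interstitial matrix list, with a median of 0.05 and a mean of -0.07 (camera adjusted p = 0.789), the lysyl hydroxylase Plod1 had 2.15 and tenascin Tnc 2.76.

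Markers of other cell types did not pass in the main fit. By camera, adjusted p was 0.33 for fibroblasts (median -0.39), 0.594 for mast cells, 0.709 for lymphocytes and NK cells, 0.877 for neutrophils and monocytes, 0.246 for skeletal muscle, 0.285 for luminal epithelium, 0.317 for erythroid cells and 0.988 for melanocytes. Many members had means below the highest array background (3.91, log2) in both groups. These were 8 of 10 for mast cells, 10 of 15 for lymphocytes and NK cells, and 6 of 10 for neutrophils and monocytes. Melanocytes had 9 of 15 and erythroid cells 4 of 6. For such dim lists the test could hardly show a change. Hair follicle and Schwann cell lists had adjusted p of 0.956 and 0.877, with medians of 0.08 and 0.16 and means of -0.13 and -0.19. Process lists that did not pass were cell cycle (0.902), lysosome and endocytosis (0.285), immediate early genes (0.292), Notch (0.333), TGF-beta and BMP (0.727), MHC class I (0.789), MHC class II (0.545) and ribosomal proteins (0.727). Without tumour replicate 2 the last 3 of these and the fibroblast list were called lower (camera adjusted p = 0.00705, 0.00144, 0.0156 and 0.0317). Relative to the healthy-skin mean, MHC class II genes averaged -1.19 and -1.15 in tumour replicates 1 and 3 but 1.12 in replicate 2. The lysosome list was called higher in 4 alternatives and the immediate early genes lower in 1.

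A list of cholesterol synthesis genes, written after the lipid result was seen but before its own values were, had a median of -1.86 over 17 genes (camera adjusted p = 1.99e-11 over 3 such lists, and unadjusted p = 0.0291 with an estimated correlation). Sebaceous genes (median -2.57) and keratinocyte markers (-2.39) fell on the same arrays, so the cells behind this fall are not known. The lipid list itself was not called with the hybridization-control level as a covariate (camera adjusted p = 0.445). Lss went from 8.84 ± 0.32 to 4.68 ± 2.28, Cyp51 from 8.86 ± 0.78 to 5.03 ± 1.88, and Insig1 from 7.24 ± 0.80 to 4.69 ± 0.51 (SD, n = 3 arrays per group).

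Keratinocyte genes did not move alike in tumour replicate 1; the genes given here were chosen after their values were seen, and no test was run on them. Krt5 had 10.53 there, against 10.74, 10.02 and 10.02 in healthy skin, and 9.02 and 6.50 in tumour replicates 2 and 3. Krt14 had 9.23, against 8.52, 9.23 and 9.54, and 6.89 and 3.92. Col17a1 had 6.69, within the healthy-skin values of 4.62, 5.43 and 6.98. Other genes of the basal layer lay below all healthy-skin values in that sample, Krt15 at 5.39 against 6.47, 6.90 and 7.28, and Trp63 at 5.96 against 6.73, 6.15 and 7.30. So did the suprabasal Krt10, at 6.37 against 9.14, 9.55 and 10.28.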
